A study of Homo sapiens with 14 samples.

How the data were processed

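The series measured DNA-RNA hybrids (R-loops) in IMR90 cells, an established human embryonic lung fibroblast line grown in 2% oxygen. Per the labels' protocols, cytoplasmic or nuclear fractions were treated with proteinase K and RNase A, incubated with the S9.6 antibody (which binds DNA-RNA hybrids) or an isotype control, and sonicated, and libraries were built with a kit for single-stranded, low-input DNA. Cells carried a control vector (proliferating) or oncogenic RAS (senescent), and some senescent cells also carried a control hairpin (shControl) or a hairpin against the helicase DDX1 (shDDX1).

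Per the labels, the series holds 14 libraries. Peak lists of 10 were used here: 2 each of proliferating, senescent, shControl and shDDX1 cytoplasm and 1 each of proliferating and senescent nuclei. The cytoplasmic replicates are named biological replicates in the labels. No list of the 2 isotype control libraries or the 2 RNase H-treated nuclear libraries was used here, so no background measured in a control could be set beside the peaks.

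Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.10, cutadapt 4.5, Bowtie2 2.4.5 and MACS2 2.2.7.1, with the GRCh38 build. The treatment of reads with several equally good positions, the duplicate filter, the MACS2 threshold and peak mode, the control library and any removal of problem regions are not given in the sources used here. These choices decide whether repeats such as mitochondrial pseudogenes, satellites and ribosomal RNA genes can appear in a list. The deposited lists hold 1 library each, with peak positions and a whole-number score per peak that the authors' caller gave. The scale of the deposited score is not given in the sources used here. It was therefore used to rank or filter peaks and not to measure the size of a change. Where peak numbers were compared under a score filter, 1 pooled median served all lists, which takes their scores as comparable. Peak numbering ran without a gap in all 10 lists, and no list holds strand, summit or fold values. The number of reads per library is unknown, so a longer list can come from a deeper library.

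Positions were read as the deposited peaks give them and are printed counting from 1. Lists were compared by overlap of at least 1 base with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The gene table was RefSeq's for GRCh38 patch 14, with 1 record per gene and no strand, exon or sequence. Of its 59788 positioned records, 58994 could be placed on a chromosome in order of position, and the 794 that broke this order were left out. This left 19862 protein-coding genes. Without strand, the planned window at transcription start sites became 1000 bases on each side of both ends of a gene record, called gene ends here, and shares in exons and introns could not be given.

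Peak numbers per library were compared with a two-sided exact permutation test, which cannot go below p = 0.333 with 2 libraries against 2. Cytoplasmic peaks were merged across the 8 lists into regions, and a region counted as called in a library that had a peak there. The share of cytoplasmic peaks with a nuclear peak has an exact 95% binomial interval, which covers counting error only. It was set beside 10000 random placements of the same peaks on their own sequence, between the first and last peak of any list and outside stretches of 1 Mb or more without a peak, since no sequence was used to find runs of unknown bases. Nuclear lists, with 1 library per condition, were described without a test between conditions, beside 100 random placements. Gene lists were ranked as a percentile among 10000 random lists of the same size. Random lists drew genes singly, so a list of neighbouring genes, such as histone clusters, can rank as more extreme than it is. No allowance was made for the number of lists or for the 2 conditions. Tested on simulated data, 1 of 100 randomly placed lists of 29 cytoplasmic peaks passed the 95th percentile against the nuclear proliferating list, and 100 of 100 lists with 10 planted overlaps did. The 29 were the peaks of proliferating replicate 1 on primary chromosomes. Scaffold and mitochondrial peaks, peaks lying close together and the other lists were not simulated. Of random lists of 25 among 19862 genes, 6 of 100 passed the 95th percentile, and 100 of 100 lists with 8 planted members did.

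Groups, comparisons, gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, for cytoplasm, genes in or within 50000 bases of a region called in both libraries of a group. For nuclei it took the 10 protein-coding genes with the best-scoring gene-end peak in each condition, the 10 best of those with none in the other condition, up to 4 members of each gene list, and DDX1, XPO1 and HRAS. Some genes that the rule takes are not reported here. Peak classes were defined after the data had been seen, in this order: the mitochondrial genome, within 1000 bases of 1 of 486 mitochondrial pseudogene records, the ribosomal RNA gene array of chromosome 21, unplaced or unlocalised sequence, the longest stretch of a chromosome without a protein-coding gene (which often spans the centromere), and other positions. The array was taken as the 45S records with 5 kb before and 20 kb after them, also chosen after seeing the data. Alternatives changed the minimum overlap, the score filter, the sequences kept, the merging of near peaks, the window, the pairing by replicate number and the libraries included. Random lists matched on base composition and other transcript starts of a gene were planned and not run, for want of sequence and transcripts.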

Results

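The peak lists describe where the S9.6 antibody pulled down DNA from the cytoplasm and the nuclei of IMR90 lung fibroblasts. Without a list of an isotype control or RNase H-treated library, no peak could be checked to be a hybrid. The stated purpose was to find where cytoplasmic hybrids come from in proliferating and RAS-induced senescent cells, and whether the helicase DDX1 is needed for their passage out of the nucleus. The 8 cytoplasmic lists held 16 to 117 peaks and the 2 nuclear lists held 114566 and 95032. Read depth is unknown for all of them.

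Senescent cytoplasm had fewer peaks than proliferating cytoplasm. The proliferating lists held 39 and 117 peaks (78 ± 55.2, SD, n = 2) and the senescent lists 16 and 18 (17 ± 1.41, SD, n = 2). Mitochondrial sequence made up most of the senescent lists, with 1 peak across the mitochondrial genome in each and 10 and 11 peaks at mitochondrial pseudogenes, the copies of mitochondrial DNA inserted in nuclear chromosomes. Peaks at these pseudogenes numbered 14 and 13 in proliferating cells. Most of the gap between conditions lay in other sequence: unplaced or unlocalised scaffolds held 9 and 28 proliferating peaks against 0 and 1, the longest gene-free stretches 8 and 40 against 5 and 5, and other chromosomal positions 6 and 32 against 0 and 0. The difference in means was -61 peaks (exact permutation test, two-sided, p = 0.333 with n = 2 per group, the smallest value this design allows). Without proliferating replicate 2 the difference was -22 peaks, without proliferating replicate 1 it was -100, and among peaks at or above the median score of all cytoplasmic peaks it was -18 (exact permutation p = 0.333). Covered length was 69.7 ± 34.3 kb in proliferating and 29.99 ± 0.368 kb in senescent cytoplasm (SD, n = 2).

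**Figure D1:**
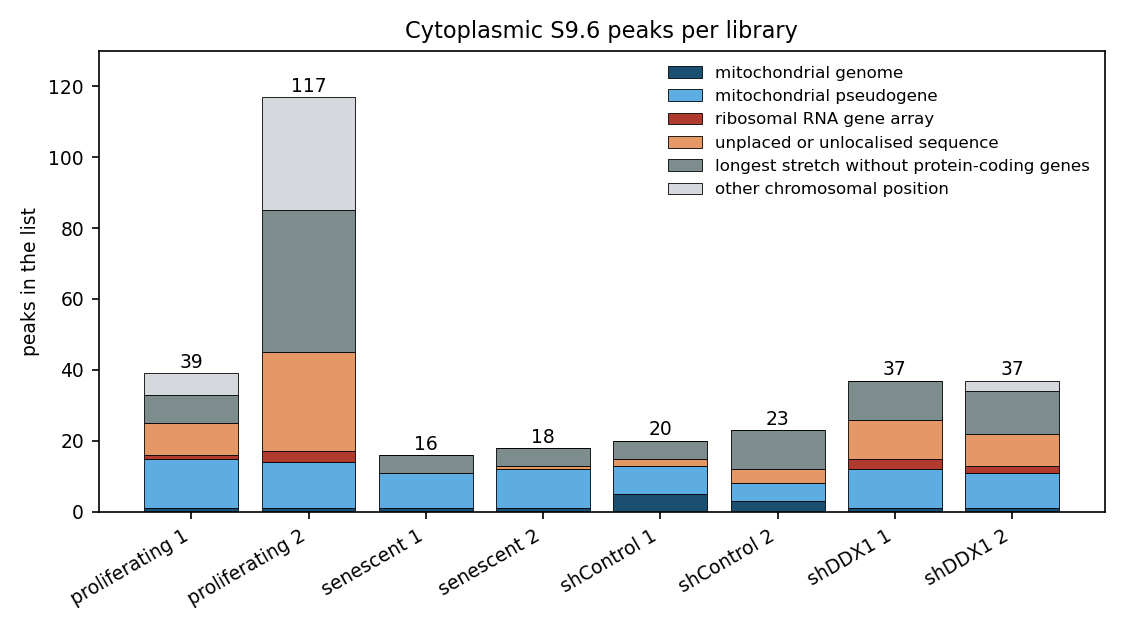
Number of peaks in each of the 8 cytoplasmic lists (bars, 1 library each), divided by where the peaks lie. The senescent lists hold 16 and 18 peaks and the proliferating lists 39 and 117.

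The mitochondrial genome was the best-scoring cytoplasmic position by the deposited score in all 8 libraries. In both proliferating, both senescent and both shDDX1 libraries 1 peak of 16254 to 16465 bases spanned nearly all of it and covered all 37 mitochondrial genes. The shControl libraries differed: replicate 1 had 5 peaks over 13179 bases with 27 genes wholly covered, and replicate 2 had 3 peaks over 4651 bases with 9 genes wholly covered and 25 uncovered. The peaks of shControl replicate 2 lay at positions 395 to 3329, 13621 to 14774 and 15780 to 16341, and the first of these holds the large ribosomal RNA gene RNR2.

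Merging gave 150 cytoplasmic regions, of which 100 were called in 1 library and 5 in all 8. These 5 were the mitochondrial genome (52 to 16516) and 4 copies of RNR2, the mitochondrial large ribosomal RNA gene. They included MTRNR2L8 (chromosome 11, 10508897 to 10510302), MTRNR2L12 (chromosome 3, 96617180 to 96618517) and a region 26 bases from MTRNR2L1 (chromosome 17, 22522663 to 22523389). A cluster on chromosome 1, with MTND1P23 and MTND2P28 at 629302 to 630023 and MTCO1P12 at 630755 to 631376 and 631880 to 632668, was called in 7 libraries, the exception being shControl replicate 2. The microRNA gene MIR12136 lies in the last of these regions. MTCO1P2, a copy of the cytochrome oxidase gene COX1 inside the anchoring-protein gene AKAP6 (chromosome 14, 32484333 to 32485106), was called in 6 libraries and in neither shControl library. MTCO1P53 (chromosome X, 126471762 to 126472706) and the MTCYBP18, MTND6P4 and MTND5P11 cluster inside PCBD2 (chromosome 5, 134923575 to 134924817) were each called in 5.

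Regions called in both libraries of both conditions numbered 10, and these were the mitochondrial genome and 9 mitochondrial pseudogene regions. Another 13 regions were called in both proliferating and neither senescent library, and 0 in both senescent and neither proliferating library, in lists of unequal length. The 13 comprised 1 pseudogene region (MTND5P11 and MTND4P12 inside PCBD2, chromosome 5, 134925172 to 134927220), 1 region in the ribosomal RNA gene array, 4 on scaffolds, 5 in gene-free stretches and 2 elsewhere. The array region overlapped the record LOC110467529 (chromosome 21, 8259510 to 8260085). Those near a gene record were at 143262324 to 143262921 and 143263647 to 143264161 on chromosome 1, 36597 and 35357 bases from LOC101929814, at 10102 to 11784 on chromosome 5, 13394 bases from LOC124900928, and at 49149161 to 49149811 on chromosome 4, 11459 bases from LOC101927209.

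**Figure D2:**
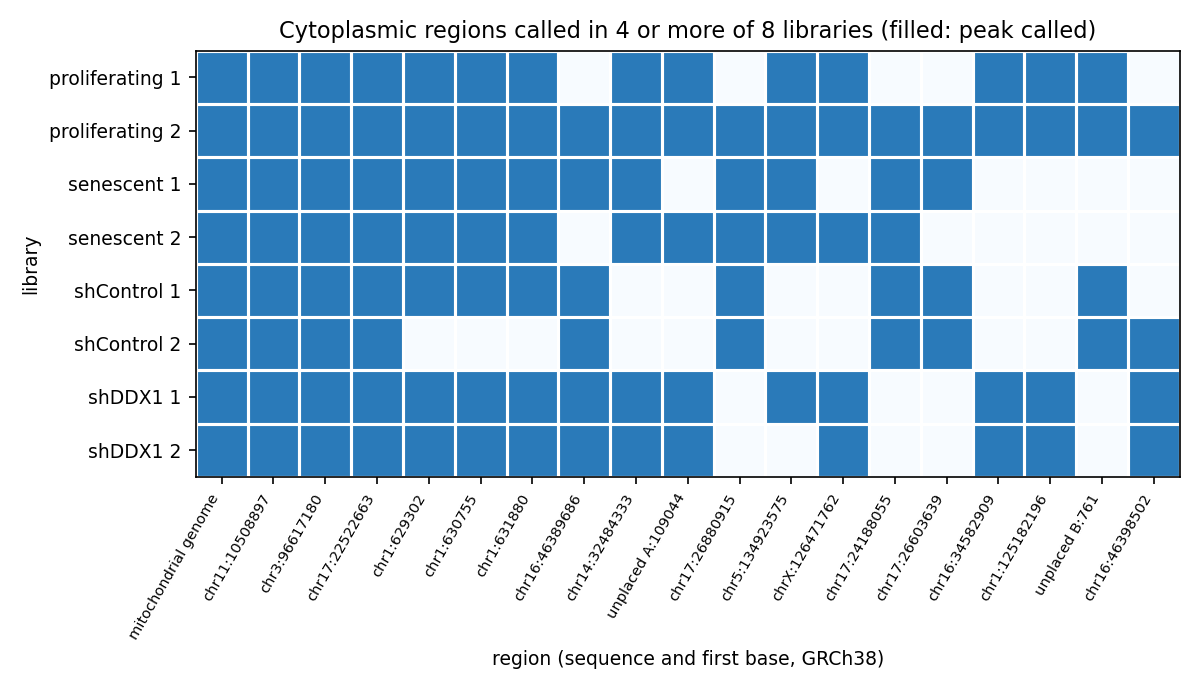
Cytoplasmic regions called in 4 or more of the 8 libraries (columns, by sequence and first base; unplaced scaffolds carry letters; 1 region left out), with a filled square where a library (row) has a peak. The first 4 columns are filled in all 8 libraries, and the chromosome 17 regions at 24188055, 26603639 and 26880915 are empty in both shDDX1 libraries.

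The hairpin comparison asked whether cytoplasmic hybrids of senescent cells change when DDX1 is knocked down. The shDDX1 lists were longer than the shControl lists: 37 and 37 peaks (37 ± 0, SD, n = 2) against 20 and 23 (21.5 ± 2.12, SD, n = 2), a ratio of 1.72. Of the shControl peaks 5 and 3 were pieces of the mitochondrial genome, a single peak in each shDDX1 library, and without it the lists held 36 and 36 peaks against 15 and 20, a ratio of 2.06. Peaks in the ribosomal RNA gene array numbered 3 and 2 with shDDX1 and 0 and 0 with shControl, and scaffold peaks 11 and 9 against 2 and 4. Pseudogene peaks numbered 11 and 10 with shDDX1 and 8 and 5 with shControl. The difference in means was 15.5 peaks (exact permutation test, two-sided, p = 0.333, n = 2 per group, the smallest value possible). With any 1 library left out it was 14 to 17 peaks, but among peaks at or above the median score of all cytoplasmic peaks it was 1 peak (exact permutation p = 1). Without the mitochondrial genome, a choice made after seeing the data, the difference was 18.5 peaks over all scores and 4 at or above that median (exact permutation p = 0.333 for both). The level of DDX1 itself was not measured by this assay, so the knockdown was not checked here.

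Which regions were called also differed between the hairpins. Both libraries of both hairpins shared 6 regions: the mitochondrial genome, the 4 RNR2 copies and a gene-free region at 46389686 to 46391289 on chromosome 16. Another 17 regions were called in both shDDX1 and neither shControl library. They included MTCO1P2, MTCO1P53, a region 4374 bases from CDC27P9 (chromosome 21, 8233968 to 8234860) and 1 over CDC27P10 (chromosome 21, 8420222 to 8420594), the last 2 in the ribosomal RNA gene array. The 17 also held 8 scaffold regions and 5 in gene-free stretches, among them 34582909 to 34583752 on chromosome 16 and 125182196 to 125183074 on chromosome 1. In the other direction 5 regions were called in both shControl and neither shDDX1 library, 2 on scaffolds and 3 in the gene-free stretch of chromosome 17, at 24188055 to 24188703, 26603639 to 26604289 and 26880915 to 26885645. The first and last of these chromosome 17 regions were also called in both senescent libraries without a hairpin, and all 3 in proliferating replicate 2. All 22 regions called in exactly 2 of the 4 libraries fell to a hairpin pair (17 and 5) and 0 to a mixed pair. The lists differ in length, and regions close together, as on chromosome 17 and at 125178909 to 125183074 on chromosome 1, may be gained or lost together. The 22 are therefore not independent of each other.

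Replicate libraries shared many of their peaks, and so did libraries of different groups. As a share of the shorter list, overlap was 64.1% for proliferating, 87.5% for senescent, 70% for shControl and 81.1% for shDDX1 replicates, a mean of 75.7 ± 10.6% (SD over 4 pairs). The 24 pairs from different groups had a mean of 67.1 ± 16.3% and ranged from 37.8 to 100%. Among peaks at or above the median score the means were 74.9 and 60.5%. Mitochondrial sequence made up much of this sharing. Regions called in both replicates numbered 25 in proliferating and 12 in senescent cytoplasm, and the mitochondrial genome and the same 9 pseudogene regions were part of both counts. Sharing was not computed without mitochondrial sequence. Pairs that share a library are not independent, and the share also depends on list length, with up to 100% for pairs with the list of 117 peaks.

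To ask whether cytoplasmic peaks match nuclear ones, each cytoplasmic list was set against the nuclear list of its condition. Peaks on the mitochondrial genome or its pseudogenes mostly had no nuclear counterpart (0 to 14.3% of them did), while most other cytoplasmic peaks did. Counting all peaks, 41.03% (16 of 39, exact 95% interval 25.6 to 57.9%) and 74.4% (87 of 117, 65.5 to 82.0%) overlapped in proliferating cells, and 37.5% (6 of 16, 15.2 to 64.6%) and 27.8% (5 of 18, 9.69 to 53.5%) in senescent cells. The shares were 30% (6 of 20, 11.9 to 54.3%) and 39.1% (9 of 23, 19.7 to 61.5%) with shControl, and 48.6% (18 of 37, 31.9 to 65.6%) and 59.5% (22 of 37, 42.1 to 75.2%) with shDDX1. Random placement gave a mean of 0.62 to 13.9 overlapping peaks per list, and at most 28 of 10000 placements reached the observed number in any list. The placements moved peaks singly, whereas some cytoplasmic peaks lie close together, as at 46386276 to 46391289 on chromosome 16, and can match the same nuclear peak. The random spread is therefore too narrow and these frequencies are too small. Senescent and proliferating shares differed by -25.1 percentage points and shDDX1 and shControl shares by 19.5 (exact permutation test, p = 0.333 for each, n = 2 per group).

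Without mitochondrial sequence, a choice made after seeing the data, the mean share with a nuclear peak of the same condition was 72.5 ± 14.2% in proliferating, 83.3 ± 23.6% in senescent, 72.9 ± 18.2% in shControl and 76.3 ± 11.7% in shDDX1 cytoplasm (SD, n = 2). The senescent share then rests on 5 of 5 and 4 of 6 peaks. The difference between senescent and proliferating shares changed sign, to 10.8 percentage points (exact permutation test, p = 0.667), and that between shDDX1 and shControl fell to 3.45 (p = 1), so both differences over all peaks depend on how much mitochondrial sequence a list holds. By class and against either nuclear list, 6 of 6 array regions, 36 of 40 scaffold regions, 40 of 52 regions in gene-free stretches and 32 of 36 other chromosomal regions had a nuclear peak, against 3 of 15 pseudogene regions. The 3 were the PCBD2 regions. The proliferating nuclear list held a peak at 1 of 5 and 1 of 6 of these senescent cytoplasmic peaks (exact 95% intervals 0.505 to 71.6% and 0.421 to 64.1%), at 2 of 7 and 4 of 15 shControl ones (3.67 to 71.0% and 7.79 to 55.1%) and at 24 of 25 and 25 of 26 shDDX1 ones (79.6 to 99.9% and 80.4 to 99.9%). The chromosome 17 regions at 24188055, 26603639 and 26880915 each had a peak in the senescent nuclear list and none in the proliferating one. Most of the 36 other chromosomal regions overlapped no gene record. Many lay close together, at 49096802 to 49154977 on chromosome 4, 31052220 to 31069219 on chromosome 20 and 90387849 to 90398759 on chromosome 2. They were not screened for repeats, so a match at ordinary chromosomal sites is not shown.

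**Figure D3:**
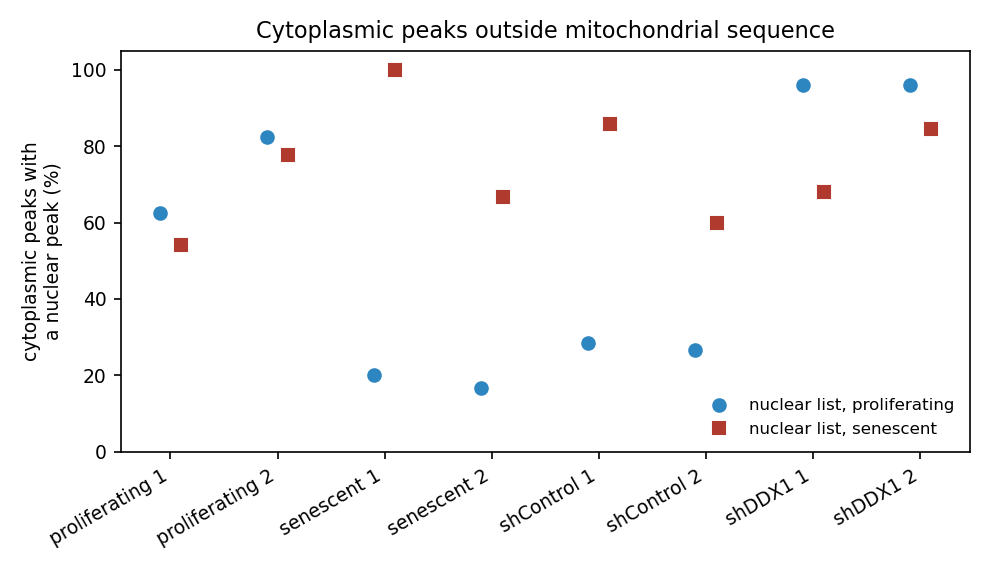
Percentage of cytoplasmic peaks outside mitochondrial sequence that overlap a peak of the proliferating (circles) or senescent (squares) nuclear list, for each of the 8 cytoplasmic libraries. With the proliferating list the senescent libraries have 1 of 5 and 1 of 6 peaks and the shDDX1 libraries 24 of 25 and 25 of 26.

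The nuclear lists compare S9.6 peaks across the genome in proliferating and senescent cells, with 1 library per condition and so no replicate check. The senescent list was shorter, with 95032 peaks over 58.0 Mb against 114566 peaks over 77.7 Mb in proliferating nuclei, ratios of 0.829 and 0.746. Its peaks were narrower, at a mean of 610 against 678 bases. Of the proliferating peaks 32.0% overlapped a senescent one (Wilson 95% interval 31.7 to 32.3%) and of the senescent peaks 39.0% a proliferating one (38.7 to 39.3%), where random placement gave 4.34% and 5.31%. Among the 1000 best-scoring peaks of each list 66.6% and 64.2% were shared. Peaks on the mitochondrial genome numbered 0 in both lists.

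Nuclear peaks were sparse on gene-rich chromosomes. Chromosome 19 held 17.7 and 13.9 peaks per Mb in proliferating and senescent nuclei, chromosome 17 held 22.9 and 19.1, and chromosome 4 held 45.3 and 38.3. Across 23 chromosomes, which are not independent replicates, peak density and protein-coding gene density were related with Pearson r = -0.838 in proliferating nuclei (permutation p = 1e-05, Benjamini-Hochberg adjusted over 2 lists 1e-05) and -0.862 in senescent nuclei (permutation p = 1e-05, adjusted 1e-05). A p of 1e-05 is the smallest the permutations can give. Spearman's rho was -0.706 (permutation p = 0.0002, adjusted 0.0002) and -0.773 (permutation p = 8e-05, adjusted 0.0002). Leaving out chromosomes 19 and 17, the farthest from the median, r was -0.699 and -0.727. Gene ends carried 1.79% of proliferating and 2.74% of senescent peaks, against 3.10% and 3.00% at random, and 39.4% and 39.7% of peak centres lay in protein-coding records against 43.2% and 43.1%.

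**Figure D4:**
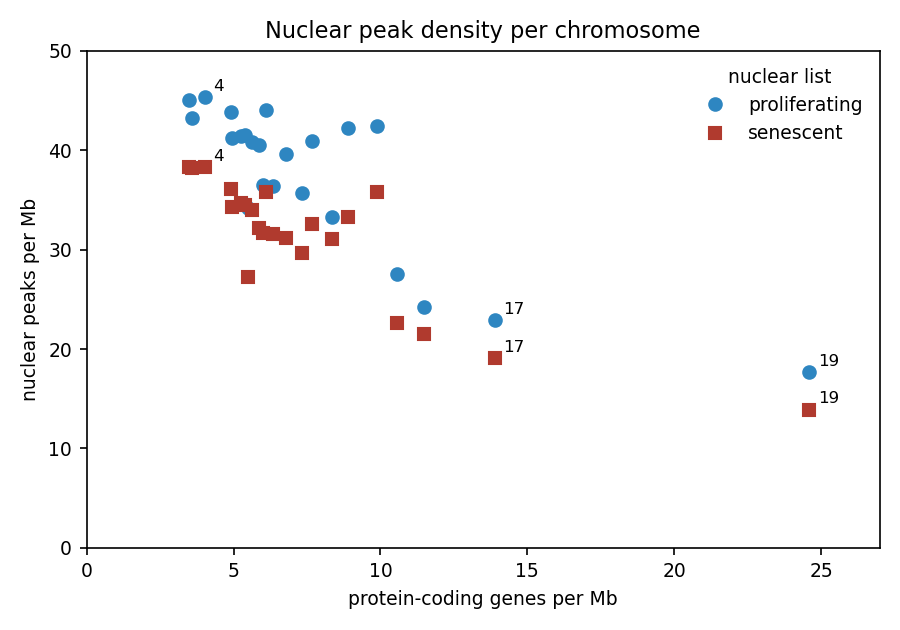
Nuclear peaks per Mb against protein-coding genes per Mb for 23 chromosomes (points) in the proliferating (circles) and senescent (squares) lists. Chromosome 19, with 24.6 genes per Mb, has 17.7 and 13.9 peaks per Mb.

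A large local difference between the nuclear lists was at the ribosomal RNA genes, picked out after seeing the data. The array on chromosome 21 (8200989 to 8466572) held 29 proliferating peaks over 29667 bases and 1 senescent peak over 419 bases. On 2 scaffolds that hold further copies the counts were 13 against 1 and 9 against 1. Of the 29 peaks, 26 lay outside the 45S precursor records, and 3 lay in the 28S parts of RNA45SN3 (2 peaks) and RNA45SN1 (1 peak). RNA45SN2 had 0 peaks in both lists. Cytoplasmic peaks in the chromosome 21 array numbered 1 and 3 in proliferating, 3 and 2 in shDDX1, and 0 in each of the 2 senescent and 2 shControl libraries. On the first of the 2 scaffolds they numbered 2 and 2 in proliferating and 1 and 0 in shDDX1 libraries. On the second they numbered 2 and 4 in proliferating and 2 and 2 in shDDX1 libraries. The senescent and shControl libraries had 0 on both. These scaffold peaks are counted above as scaffold peaks and not as array peaks.

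**Figure D5:**
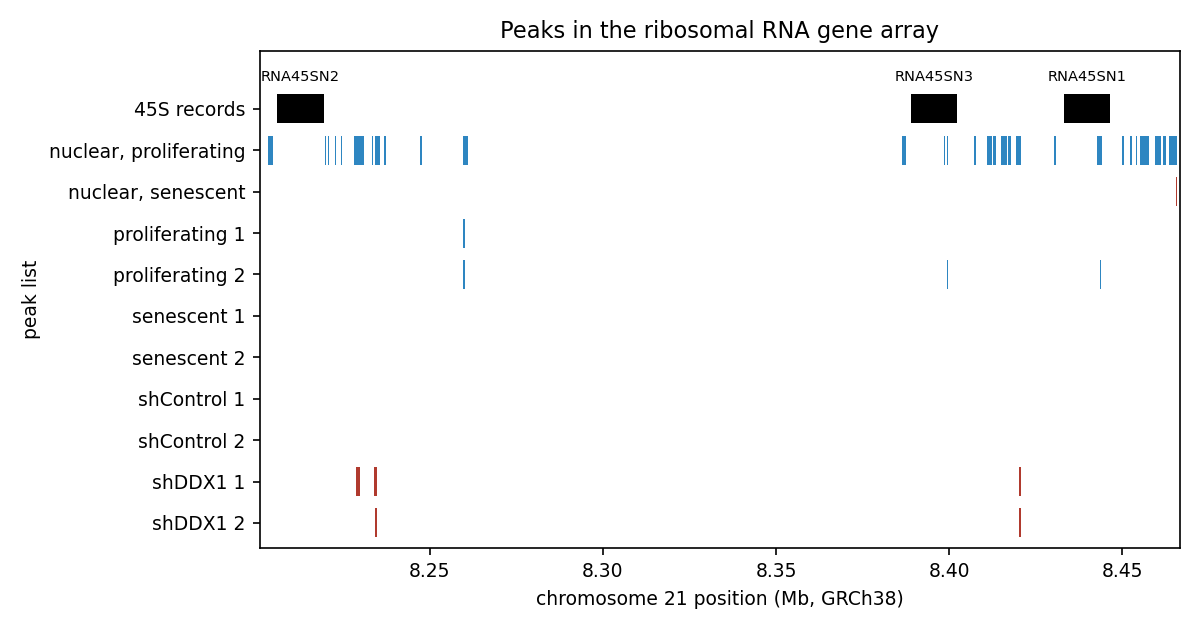
Peaks (bars, to scale) in the ribosomal RNA gene array of chromosome 21 in the 2 nuclear and 8 cytoplasmic lists, with the 45S precursor records above. The proliferating nuclear list has 29 peaks here and the senescent nuclear list 1.

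At gene ends, 2045 protein-coding genes had a peak in proliferating and 2635 in senescent nuclei, and 861 had one in both, where 271 would be shared by independent lists. The best-scoring gene-end peaks included those at LOC101929601 (chromosome 8, 85735314 to 85737397) and GAGE12B, a cancer-testis antigen gene (chromosome X, 49341164 to 49529982), in both lists, with PRR20B, LOC124907867 and FAM90A19 high in the proliferating list and with gene-end peaks in the other. The senescent list also had LOC124902048, FAM90A8, GAGE2A and WASHC1, which encodes a subunit of the WASH complex, near its top, with gene-end peaks in the proliferating list too. Gene-end peaks of the proliferating list with none in the senescent list were best-scoring at AADAC, an arylacetamide deacetylase gene (chromosome 3, 151814116 to 151828488), CYP4F12, a cytochrome P450 gene (chromosome 19, 15673087 to 15697174), SPANXN2, LOC124904970, DIRAS1, SPX, ACRV1, KRTAP21-1, ARHGAP24 and SPANXN1. In the other direction they were LOC124903130, LOC101929627, FAM90A12, DLGAP3, which encodes a postsynaptic scaffold protein (chromosome 1, 34865436 to 34929650), SUPT3H (chromosome 6, 44809057 to 45377934), LOC107986800, POTEH, DCAF12L1, and MRPL13 and MTBP, which are neighbours on chromosome 8 and share a peak. Long genes among these had peaks inside their records in both lists, such as 26 and 24 in ARHGAP24 and 28 and 14 in SUPT3H. FAM90A12 has relatives, FAM90A8 and FAM90A19, with gene-end peaks in both lists. The treatment of reads with several equally good positions is unknown, so calls in 1 condition at members of gene families are uncertain. DDX1 (chromosome 2, 15591868 to 15631101), the export receptor gene XPO1 (chromosome 2, 61477849 to 61538612) and HRAS (chromosome 11, 532242 to 535576) had no gene-end peak in either list. DDX1 held 1 peak inside its record in the proliferating list and 0 in the senescent list, XPO1 0 and 1, and HRAS 0 and 0.

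Of the 14 gene lists, olfactory receptor genes, which are mostly silent outside the olfactory epithelium, had gene-end peaks most often. Of 19, 7 had one in the proliferating and 6 in the senescent list, percentiles 99.9 and 97.9 among random lists, with OR4F5 and OR5A1 in both, OR6A2 in the proliferating and OR8B8 in the senescent list. With peaks at or above the pooled median score the percentiles were 93.9 and 97.46, inside the central 95% of random lists, and for a peak anywhere in the gene against lists matched on gene length, an alternative added after seeing the data, the senescent one was 94.9. Histone genes of the replication-dependent clusters had none (0 of 33 in each list, percentiles 1.24 and 0.425). This too was lost with a window of 500 bases (8.30 and 3.03) and with the score filter (6.61 and 4.28), and in the proliferating list with a window of 2000 bases (19.025) and for a peak anywhere in the gene (15.4). Cytosolic ribosomal protein genes had 3 and 2 of 53 (13.4 and 1.31; in the proliferating list 1.61 with a window of 2000 bases and 1.89 with the score filter), with RPL8 in both lists, RPL5 and RPS6 in the proliferating and RPS18 in the senescent list. Genes of the senescence-associated secretory phenotype had 6 and 4 of 30 (94.3 and 52.7). The growth-factor-binding protein gene IGFBP5 and the chemokine gene CCL20 had gene-end peaks in both conditions, the protease gene MMP3 in proliferating and the cytokine gene IL1A in senescent nuclei.

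The remaining lists lay within the central 95% of random lists in both conditions with the window of 1000 bases. Proliferation genes had 1 and 1 of 24 (percentiles 17.4 and 8.93), both at the replicative helicase gene MCM7. Senescence and p53 genes had 1 and 3 of 18 (28.8 and 68.0), with BTG2 in the proliferating and HMGB1, HMGB2 and SESN1 in the senescent list. Nucleic acid sensing and interferon genes had 3 and 2 of 25 (63.3 and 23.5), with RIGI in the proliferating and OAS2 and TLR3 in the senescent list. R-loop processing and nuclear export genes had 0 and 1 of 24 (3.67 and 8.93), the 1 being the nuclease gene ERCC5. Immediate early genes had 0 and 1 of 25 (3.30 and 8.08), the 1 being EGR1. Fibroblast matrix genes had 2 and 2 of 22 (46.2 and 30.7), with DCN and COL5A2 in the proliferating and COL1A1 and SPARC in the senescent list, and for a peak anywhere in the gene the proliferating percentile was 1.19. Loci commonly positive in R-loop pull-downs had 1 and 0 of 10 (52.8 and 12.0), at TRIM33. For a peak anywhere in the gene they had 1 and 1 of 10 (16.6 and 12.6 among length-matched lists), so they showed no excess of peaks. Markers of other cell types were 1 and 0 of 16 for epithelial genes (33.7 and 5.05, the latter 1.16 with a window of 2000 bases and 1.72 for a peak anywhere in the gene, at CLDN7), 3 and 4 of 16 for haematopoietic genes (85.1 and 89.8, but 98.04 and 98.9 for a peak anywhere in the gene, with SPI1 and CD3E in both lists) and 1 and 1 of 16 for neuronal genes (33.7 and 22.5, at NEUROD1 and GRIN2B).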

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

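The alternatives without mitochondrial sequence or the mitochondrial genome and those on gene length were chosen after seeing the data. Of the values that answer a comparison 92 stayed within the replicate spread, the interval or 1.5 times the main value, 36 moved and 1 reversed. The reversed one is the senescent minus proliferating share of cytoplasmic peaks with a nuclear peak, which went from -25.1 to 10.8 percentage points without mitochondrial sequence (-41.7 to -8.39 with 1 library left out). The shDDX1 minus shControl share, 19.5 points, became 3.45 without mitochondrial sequence, 8.67 on primary chromosomes and 52.5 with the proliferating nuclear list (14.1 to 24.9 with 1 library left out). The peak-number differences kept their sign and fell from -61 to -18 (senescent minus proliferating) and from 15.5 to 1 (shDDX1 minus shControl, exact permutation p = 1) with the score filter. With the filter and without the mitochondrial genome they were -18 and 4. Covered length differed by -39.7 kb (senescent minus proliferating). Peak-number differences ran from -100 to -22 peaks (senescent minus proliferating) and from 14 to 17 (shDDX1 minus shControl) with 1 library left out, and -61 and 15.5 with the replicate block by replicate number (exact sign-flip permutation p = 0.5 for both, the smallest 2 pairs allow). The labels give the numbers no shared day or batch, and 2 libraries per group are too few to check the pairing. The share of cytoplasmic peaks with a nuclear peak of the same condition moved in senescent cells from 32.6% to 23.6% when 0.5 of the peak had to overlap, in shControl cells from 34.6% to 41.1% on primary chromosomes, and without mitochondrial sequence to 83.3% (senescent), 72.9% (shControl) and 76.3% (shDDX1, from 54.1%). Over all peaks, mitochondrial ones included, the shares with the proliferating nuclear list in place of the senescent one were 5.90% (senescent), 13.7% (shControl) and 66.2% (shDDX1). Placement over the whole genome, which also moved peaks singly, reached the observed overlap in at most 20 of 10000 draws. The shared share of nuclear peaks, 32.0% of the proliferating and 39.0% of the senescent list, became 17.8% and 27.5% with the score filter, 33.6% and 34.0% with equal numbers of peaks, 32.8% and 39.5% after merging, and 22.7% and 27.3% with reciprocal overlap. Gene ends held 0.923% and 1.66% of peaks with a window of 500 bases and 3.34% and 4.48% with 2000, by construction, and 3.20% of senescent peaks with the score filter, which also moved the share of proliferating peak centres in protein-coding records to 39.0%. Gene lists above the central 95% of random lists, 1 in each condition, became 0 and 0 with the score filter, and 2 in the proliferating list for a peak anywhere in the gene with length-matched lists. Those below it, 1 and 2, became 0 and 1 with the 500-base window, and 1 in the senescent list with the score filter, while the senescent count rose to 3 with the 2000-base window and for a peak anywhere in the gene. For single gene lists, 152 percentiles stayed on their side of these limits, 9 were weaker, all for histone or olfactory receptor genes, and 7 stronger, for ribosomal protein, epithelial, haematopoietic and fibroblast matrix genes. Apart from the changes that follow from the construction of a window or overlap rule, the cause was not tested. Unknown depth limits every count, since a deeper library yields more peaks. Equal numbers of peaks fix the ratio of nuclear peak numbers, and random lists matched on base composition and other transcript starts were not run.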

Other observations

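The counts in the first 2 paragraphs, and all tests below except those on clearing of the nuclear lists and on nuclear score ranks, were chosen after the results were seen. Nuclear peaks were frequent at mitochondrial pseudogenes, although the mitochondrial genome itself had 0 nuclear peaks. Merged within 1000 bases, the pseudogene records form 183 stretches on the chromosomes, and 65 of them had a peak in the proliferating and 56 in the senescent list, where 1000 random placements gave means of 19.4 and 15.998 and highest values of 32 and 30. Stretches with peaks in both lists included MTCO3P39 and MTND3P22 (chromosome 4, 49246021 to 49246915), MTCO3P42 (chromosome 4, 49548918 to 49549435), MTCO1P47 and MTND2P35 (chromosome 8, 110933263 to 110935638) and a stretch of 12207 bases from MTCYBP17 to MTND1P22 (chromosome 4, 155451617 to 155463823). Of the 15 pseudogene regions called in the cytoplasm, 3 had a nuclear peak.

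The regions that set the hairpins apart can be followed into the other libraries. Of the 17 regions called in both shDDX1 and neither shControl library, 10 were called in a proliferating and 3 in a senescent library without a hairpin, and 15 overlapped a proliferating and 11 a senescent nuclear peak. Over all 150 regions, most of them from the longest list, these numbers were 126, 17, 104 and 95. Of the 5 called in both shControl and neither shDDX1 library, 4 were called in a proliferating and 3 in a senescent library, and 1 overlapped a proliferating and 4 a senescent nuclear peak. The shDDX1 and proliferating libraries both had peaks in the ribosomal array, at different positions within it, and the shControl libraries shared the chromosome 17 regions at 24188055 and 26880915 with both senescent libraries and proliferating replicate 2.

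Cytoplasmic peaks at mitochondrial pseudogenes appeared in all 8 libraries. One explanation, reads of mitochondrial DNA placed on nuclear copies, was examined in shControl replicate 2, whose mitochondrial peaks are partial: 0 of the 6 pseudogene regions whose parent genes lay wholly outside those peaks and 0 of the 3 whose parents were partly covered were called there, against 4 of the 6 whose parent was wholly covered (outside against wholly covered, Fisher's exact test, p = 0.0606). Misplaced mitochondrial reads would give this pattern, but it rests on 1 library and on 1 parent gene, RNR2, for all 6 wholly covered regions. Some of the regions with uncovered parents also went uncalled elsewhere under full cover. MTCO1P2 and MTCO1P53 did so in shControl replicate 1 (1542 of 1542 parent bases), and MTCO1P53 also in senescent replicate 1. The MTATP8P1 and MTATP6P1 region did so in proliferating replicate 2, senescent replicate 1 and both shDDX1 libraries (888 of 888). The MTND4P12, MTND4LP30 and MTND3P25 region inside PCBD2 did so in proliferating replicate 1, both senescent and both shDDX1 libraries (2021 of 2021). For these last regions a missing call in shControl replicate 2 says little. Both MTCO1P12 regions were called in the 7 other libraries. Clearing of all mitochondrial-like positions from the nuclear lists is argued against, because annotated mitochondrial pseudogenes had nuclear peaks more often than any of 10000 length-matched random pseudogene lists (percentile 100). Hybrids formed at these loci in the nucleus stay open: 20% of the pseudogene regions had a nuclear peak (exact interval 4.33 to 48.1%) against 85.1% of other regions (77.9 to 90.6%), but lists with 0 mitochondrial peaks may also miss its closest copies, a reservation added after these shares were seen and had first been read as against nuclear formation.

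The ribosomal RNA gene arrays had many proliferating and few senescent nuclear peaks. A shorter or less deep senescent list as the cause predicts that array peaks are shared about as often as other peaks of like score. Of the 51 proliferating array peaks 3.92% overlapped a senescent peak. Score-matched sets of other proliferating peaks gave 77.9% (central 95% of sets 68.6 to 86.3%). The sets drew peaks singly, whereas the 51 lie in copies of the same array and may be gained or lost together. The interval is therefore too narrow, and this explanation stays open. Reads moved to the copies on 2 scaffolds are argued against as the whole cause, as covered bases in the counted parts of these scaffolds were 3.07% of the proliferating value. A narrow pile-up stays open, because covered bases do not show its height. The single senescent peak in the counted part of 1 scaffold (439 bases) scored 2808 against at most 685 in the proliferating list. On the other scaffold the scores were 180 and at most 1309. Scores of unknown scale cannot be compared between lists, so these values decide nothing. Copy number, or the control library used in peak calling, cannot be told apart from a change in hybrids, because 0 read-depth tracks were used here. A difference between the conditions remains open as a hypothesis, untested with 1 library each.

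Of the 134 cytoplasmic regions outside mitochondrial sequence, 114 overlapped a nuclear peak and 20 did not. Carry-over of nuclear material and export of hybrids from the nucleus both predict overlap with high-ranking nuclear peaks, and the overlapped peaks had a median score percentile of 99.9 (quartiles 99.86 and 99.97). Random placement on the same sequences already gave a median of 96.7, above the bound of 95 set beforehand, so the test decides nothing, and the 2 explanations cannot be told apart. The comparison with random placement was added after the percentile was seen, which by the bound alone had been read as in favour of both. Collapsed repeats that give peaks in any library are a further possible explanation, not tested here without the isotype control.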
